A study of Mus musculus with 6 samples.

How the data were processed

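RNA from MCT mouse proximal tubular cells was measured on Affymetrix whole-transcript arrays, 3 from vehicle-treated cells and 3 from cells given 100 ng/mL TWEAK for 6 h. Groups and replicate numbers were taken from the sample titles. Total RNA was extracted with Trizol and labelled with a GeneChip WT PLUS kit, per the labels' protocols. The series text describes 3 independent experiments, and p-values here measure the spread between those arrays.

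The authors deposited log2 expression values per probe set and array, made with RMA in Affymetrix Expression Console, per the submitters' processing notes; versions, the annotation release and the genome build are not given in the sources used here. RMA corrects background, makes the distributions of the arrays alike and summarises probes, so that a shift shared by most transcripts would not be seen, and no measure of signal over background per probe set was used. The deposited series values and the deposited workbook held the same numbers (largest difference 1.8e-15), so the workbook was used. The same workbook holds the authors' ratio of TWEAK over control, which was tested on the file and equals the mean of unlogged TWEAK values over the mean of unlogged control values (largest relative difference 1.33e-15). It also holds the authors' p-value and false discovery rate per probe set, per the file headers. These p-values equal those of limma without a replicate block over all probe sets (largest difference 3.87e-13 in log10), and the rate equals a Benjamini-Hochberg adjustment.

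Of 28361 probe sets, 25465 had 1 gene symbol in the file, 2894 had none and 2 had several. Symbols were updated through a RefSeq gene table of assembly GRCm38.p6, used for names only: 22111 probe sets were matched by accession, 1818 by symbol and 625 by synonym, 911 kept the name in the file, and 2970 symbols changed, among them that of Smarca5-ps, Vmn2r-ps14 in the file, by its accession. No gene was named from a probe set with several symbols or none, and 91 probe sets of an unmapped category were treated like the others. A gene with several probe sets, 1845 of them, was represented by the probe set with the highest mean over all 6 arrays, leaving 22061 genes and no filter on dim ones. Of 59 changed genes with several probe sets, 9 had a probe set of opposite sign. Families of similar copies such as the H2, Gbp and Sprr genes are uncertain on these arrays.

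Differences (TWEAK minus control) were tested with limma 3.58.1 (lmFit and eBayes, no trend, not robust, no replicate block) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05; a second count also asked for a change of at least 2-fold. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. A fold is 2 to the power of the difference of log2 means, and SE is the moderated standard error. Gene lists, 25 in number, were fixed before the data were examined: NF-kB pathway, chemokines, cytokines and growth factors, adhesion molecules, TNF receptors and cell death, immediate early and AP-1 genes, interferon response, antigen presentation, complement and acute phase, proximal tubule identity, tubular injury, matrix and mesenchymal genes, fatty acid oxidation, oxidative phosphorylation, cholesterol synthesis, cell cycle, p53 targets, unfolded protein response, antioxidant and ferroptosis genes, glycolysis and hypoxia, housekeeping, and markers of leukocytes, endothelium, fibroblasts with pericytes, and distal nephron with podocytes. All members were measured. Lists were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists, again with an estimated correlation, which called 0 lists (4 at an unadjusted p under 0.05), and with fry.

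Genes were named by a rule also fixed before the data were examined: the 12 largest rises and the 10 largest falls among genes past the threshold whose groups of arrays did not overlap; Tnfrsf12a, Tnfsf12, Ccl2, Ccl5, Cxcl16, Nfkbiz, Bcl3, Kl and Ppargc1a whatever their values; and up to 4 members with the smallest p from each list, of which 1 gene is not reported here. Any other gene is said to have been chosen after its values were seen. The code was tested on simulated data with the mean and limma's moderated spread of each of the 22061 genes: 100 of 100 genes raised or lowered by 1 on the log2 scale and 100 of 100 changed by 2 were recovered, with 10 false calls among 210. The simulated errors were independent and held no variation shared across genes, so this says nothing on the shared variation of the real arrays. The moderated spread is smaller than the measured one for genes of large spread, so recovery of such genes could be lower in the real data.

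Alternatives planned before the data were examined were a replicate block, eBayes with trend and robust settings, only genes brighter than the median gene, the mean of all probe sets of a gene, arrays centred on their median, cyclic loess, each array left out in turn, all probe sets tested 1 by 1, the authors' deposited results, an estimated correlation and fry. Removing the first axis of within-group variation, limma's array weights and counting genes with identical values once were added after seeing the data. The axis was found within groups, but its removal also took out the difference between the groups along it. Smaller changes or lost calls after the removal therefore do not tell variation among arrays from an effect of TWEAK. No genomic coordinates are given, because the files name no build.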

Results

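MCT cells, a mouse proximal tubular epithelial line derived from kidney cortex, were kept in serum-free medium and then given the cytokine TWEAK, a member of the TNF superfamily whose receptor is Fn14, at 100 ng/mL for 6 h, or vehicle. Affymetrix arrays measured RNA from 3 control and 3 TWEAK samples, which the series describes as independent experiments. The question was which transcripts respond to TWEAK in tubular cells. The 28361 probe sets gave values for 22061 named genes. The median log2 value per array lay between 6.12 and 6.18, and the number of arrays limits the precision. Correlation across genes, which are not independent replicates, was 0.992 to 0.996 among the control arrays, 0.993 to 0.996 among the TWEAK arrays and 0.980 to 0.995 between the groups. The first principal component held 61.2% of the variance, with scores of -3.26, -20.1 and -36.8 for control 1, 2 and 3 and of 20.3, 9.37 and 30.5 for TWEAK 1, 2 and 3.

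After 6 h of TWEAK the adhesion molecule Vcam1, which binds leukocyte integrins, rose 13.6-fold, from a mean log2 value of 6.17 ± 0.32 in the control cells to 9.93 ± 0.62 (SD, n = 3 arrays per group). The growth factor Csf2 (GM-CSF) rose 6.27-fold, the TNF receptor adaptor Traf1 5.87-fold, the tight junction protein Cldn1 4.38-fold and the T cell chemokine Ccl5 4.23-fold. Of 23 NF-kB pathway genes 11 rose, and so did 7 of 15 genes of antigen presentation by class I molecules, counts that rested on single arrays as given below. The genes that fell most were Cul4b, a scaffold of ubiquitin ligases, at 3.06-fold lower, the focal adhesion protein Lpp at 2.71-fold lower, and the mitotic genes Spc25 and Kif11 at 2.64-fold and 2.54-fold lower. Cpt1a, the carnitine palmitoyltransferase that admits long-chain fatty acids to mitochondria, fell by 1.03 on the log2 scale (SE 0.13).

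In all, 661 genes changed at a Benjamini-Hochberg adjusted p under 0.05 in limma, 283 higher and 378 lower under TWEAK, and 104 of them by at least 2-fold, 58 higher and 46 lower. This fit held no replicate block, and whether the replicate numbers pair the arrays stays open. With a block fewer genes were called, more of them higher than lower, as given below. At an unadjusted p under 0.05 there were 1799 higher and 2889 lower genes. The TWEAK arrays all lay on the same side of all control arrays for 5830 genes, 26.4% of those tested, where chance gives 10%. The count of calls rested on single arrays: it was 1 without TWEAK 1, 16 without control 2, 38 without TWEAK 3, 63 without control 3, 219 without TWEAK 2 and 1876 without control 1. Sizes moved less than the count. The median of the 283 was 0.65 with all arrays, 0.66 without TWEAK 1 and 0.61 without control 3. That of the 378 was -0.71, -0.72 and -0.62. Without TWEAK 1, 3967 genes still had an unadjusted p under 0.05 in limma. Within the 25 gene lists, limma called 0 members without TWEAK 1, and without control 2 only 4 NF-kB genes, 1 chemokine and 1 adhesion molecule. Counted over all probe sets 1 by 1, 107 passed (78 higher, 29 lower), and the share of higher genes among the calls, 42.8%, was 53.4% with the arrays centred on their medians and 72.6% (183 higher, 69 lower) after cyclic loess. Of the genes that fell, 95.5% had a higher value in control 3 than in control 1, against 37.9% of all genes, and of those that rose, 85.9% had a lower value in control 3 than in control 1.

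**Figure D1:**
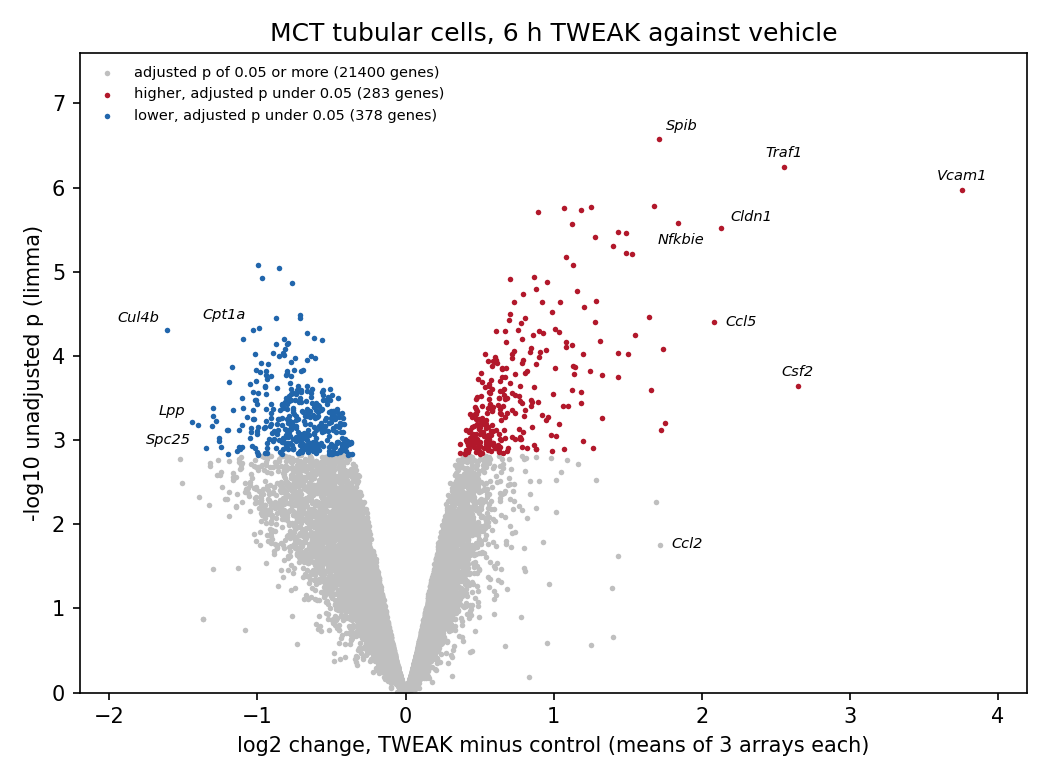
Each point is 1 of the 22061 genes, with the log2 change (TWEAK minus control, means of 3 arrays each) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. The 283 genes that were higher at adjusted p under 0.05 are red and reach 3.76 (Vcam1), and the 378 lower genes are blue and reach -1.61 (Cul4b).

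Among the 12 largest rises, Vcam1 changed by 3.76 on the log2 scale (SE 0.29) and Csf2 by 2.65 (SE 0.42), with limma's Benjamini-Hochberg adjusted p at 0.00542 and 0.0330. Traf1 rose by 2.55 (SE 0.18), Cldn1 by 2.13 (SE 0.19), Ccl5 by 2.08 (SE 0.26) and Nfkbie, an inhibitor of NF-kB, by 1.84 (SE 0.16). The remaining 6 were the lectin-like receptor ligand Clec2d (1.75, SE 0.33), the cornified envelope precursor Sprr1a (1.74, SE 0.24), the microRNA gene Mir18 (1.72, SE 0.33), the ETS family transcription factor Spib (1.71, SE 0.11), the atypical chemoattractant receptor Ccrl2 (1.68, SE 0.14) and the kinase subunit Pik3r5 (1.66, SE 0.27). Spib stayed past the threshold with each array left out in turn, with limma's Benjamini-Hochberg adjusted p at 0.0337 or less, while the other 11 lost their calls without TWEAK 1, Vcam1 at 0.0564. Csf2 ranged most among the TWEAK arrays, with an SD of 0.98 on the log2 scale, and Ccl5 most among the control arrays of these 12, with an SD of 0.60. Sprr1a and Clec2d have close relatives in the genome, which leaves their values uncertain.

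**Figure D2:**
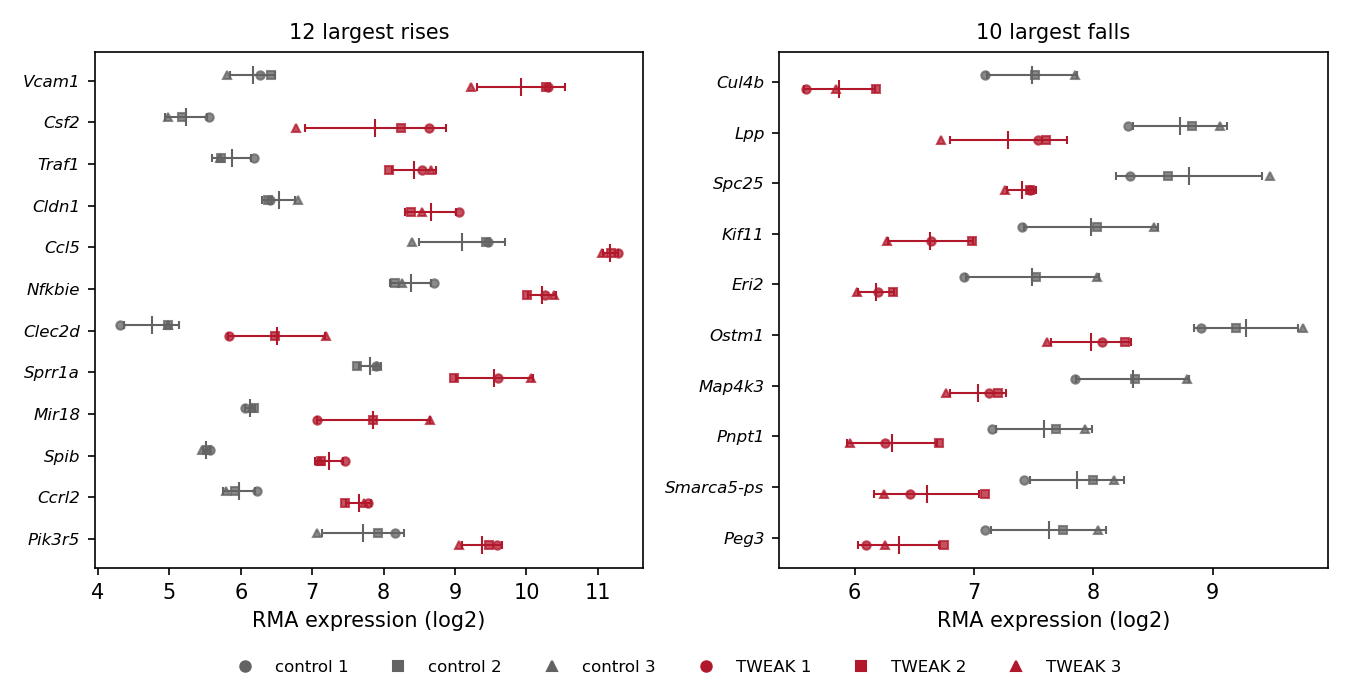
Points are the RMA log2 values of each array for the 12 largest rises (left) and 10 largest falls (right), grey for control and red for TWEAK, with a marker shape per replicate number; the upright tick and horizontal bar are the mean and SD of 3 arrays. Every TWEAK array lies beyond every control array for each gene, as the selection required, and Vcam1 moves from 6.17 to 9.93.

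The TWEAK receptor gene Tnfrsf12a was at 10.54 ± 0.20 in control and 10.88 ± 0.42 in TWEAK cells (log2, SD, n = 3), a difference of 0.34 (SE 0.20) that did not pass limma's test at a Benjamini-Hochberg adjusted p of 0.399. The Tnfrsf12a difference kept its sign in 14 of 15 alternatives and was lowest at -0.11. No probe set carried the name of the ligand gene Tnfsf12 alone, so it is not reported. Ccl2, the monocyte chemoattractant, differed by 1.72 (SE 0.58, adjusted p = 0.135 in limma with Benjamini-Hochberg adjustment), with a control SD of 1.38, and the NF-kB cofactor Bcl3 by 1.29 (SE 0.31, adjusted p = 0.0619). The NF-kB cofactor Nfkbiz differed by 0.01 (SE 0.25), the chemokine Cxcl16 by 0.05 (SE 0.10) and the anti-ageing kidney gene Kl by 0.11 (SE 0.09), none past the threshold. Nfkbiz kept its sign in 11 of 15 alternatives, Cxcl16 in 11 of 14 and Kl in 13 of 14. Cxcl16 was at 4.42 in control and 4.47 in TWEAK cells and Kl at 4.87 and 4.98. The lower quartiles of the arrays were 4.65 to 4.73, so changes of these dim genes could go unseen. Ppargc1a, a coactivator of mitochondrial genes, differed by -0.76 (SE 0.18, adjusted p = 0.0596 in limma with Benjamini-Hochberg adjustment).

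Of the 23 NF-kB pathway genes measured, 11 rose and 12 did not pass the test over all genes, while adjusted over the list alone 17 were higher and 1 lower. The 11 became 0 without TWEAK 1, 4 without control 2 and 6 without control 3 or TWEAK 3, with 17 higher at an unadjusted p under 0.05 in limma each time. The median log2 change was 0.68, and camera with a preset correlation of 0.01 called the list higher at a Benjamini-Hochberg adjusted p of 1.58e-13. The list was not called at adjusted p = 0.302 with an estimated correlation. Beside Traf1 and Nfkbie, the members with the smallest p were the kinase Map3k14 (NIK), which rose by 1.19 (SE 0.10), and Nfkb2, the precursor of a noncanonical NF-kB subunit, which rose by 1.13 (SE 0.10). The 11 held both subunits and inhibitors of the pathway, Nfkb2 and Nfkbie being examples.

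Chemokines were called higher as a list, with 3 of 24 members passing over all genes and 6 adjusted over the list alone (median 0.40, camera adjusted p = 5.20e-04). That call was lost at adjusted p = 0.539 with an estimated correlation, and at 0.0513 with the main axis of variation among arrays removed. The median then fell to 0.04 (quartiles -0.08 and 0.76, against 0.04 and 0.98 before). The chemokine median was 0.12 without control 3, 0.25 without TWEAK 1, 0.68 without control 1 and 0.73 without TWEAK 3. Beside Ccl5, the chemokines past the test over all genes were the T cell chemoattractant Cxcl10, which rose by 1.49 (SE 0.14), and the membrane-bound chemokine Cx3cl1, which rose by 1.33 (SE 0.24), whereas Ccl9 differed by 0.88 (SE 0.19, limma with Benjamini-Hochberg adjusted p = 0.0505). Among 26 cytokines and growth factors 2 rose, Csf2 and the macrophage growth factor Csf1 (0.57, SE 0.09), and adjusted over the list alone 5 were higher and 1 lower. Camera called this list higher at an adjusted p of 0.0191. The cytokine list had an adjusted p of 0.505 with an estimated correlation, 0.0691 without control 1, 0.0516 with array weights and 0.0513 with the main axis removed. The last of these moved its median from 0.13 to 0.06 (quartiles from -0.02 and 0.34 to -0.07 and 0.23). Il15 and Lif differed by 0.90 (SE 0.22) and 0.72 (SE 0.18) without passing over all genes. Of 16 adhesion molecules, 4 rose over all genes, and 6 were higher and 1 lower adjusted over the list alone (median 0.14, camera adjusted p = 0.00413). The adhesion call had adjusted p = 0.480 with an estimated correlation. Its other risers were Icam1, a ligand of leukocyte integrins, by 1.24 (SE 0.19), the hyaluronan receptor Cd44 by 0.89 (SE 0.15) and Madcam1 by 0.79 (SE 0.15).

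Immediate early and AP-1 genes had 6 of 25 members higher over all genes and 8 adjusted over the list alone, a median of 0.22 and a camera adjusted p of 3.75e-05, with adjusted p = 0.505 with an estimated correlation. The median was 0.11 without control 3, 0.12 without TWEAK 3, 0.14 with array weights and 0.07 with the main axis removed. Camera still called the list in each. Its 6 members became 3 without TWEAK 2 and 0 without control 2, control 3, TWEAK 1 or TWEAK 3, with 8 to 11 higher at an unadjusted p under 0.05 in limma. The small MAF protein Maff rose by 1.19 (SE 0.19), the AP-1 subunit Fosl1 by 0.95 (SE 0.13), Myc by 0.85 (SE 0.14) and the AP-1 subunit Junb by 0.72 (SE 0.14). Antigen presentation had 7 of 15 members higher and 11 adjusted over the list alone (median 0.36, camera adjusted p = 2.16e-08), with adjusted p = 0.302 with an estimated correlation. The 7 became 0 without control 2, TWEAK 1 or TWEAK 3, 1 without control 3 and 4 without TWEAK 2, with 10 or 11 higher at an unadjusted p under 0.05 in limma. The immunoproteasome subunit Psmb10 rose by 1.16 (SE 0.13), the peptide transporter subunits Tap2 and Tap1 by 0.70 (SE 0.09) and 0.60 (SE 0.09), and the peptide loading protein Tapbp by 0.56 (SE 0.08). Of 24 interferon response genes 3 rose, and the same number adjusted over the list alone: the transcription factor Irf1 by 0.87 (SE 0.09) and the guanylate-binding proteins Gbp2 by 1.26 (SE 0.26) and Gbp3 by 0.65 (SE 0.11), a family whose close copies make these values uncertain. Ifit1, a classical interferon-induced gene, differed by -0.42 (SE 0.15). Camera called the interferon list higher at 0.0326, with adjusted p = 0.583 with an estimated correlation, and the call was also lost without control 1 (0.145), TWEAK 1 (0.0960) or TWEAK 2 (0.277) and with array weights (0.158, with the median at 0.09 instead of 0.13). Without control 3 the interferon median was 0.07.

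**Figure D3:**
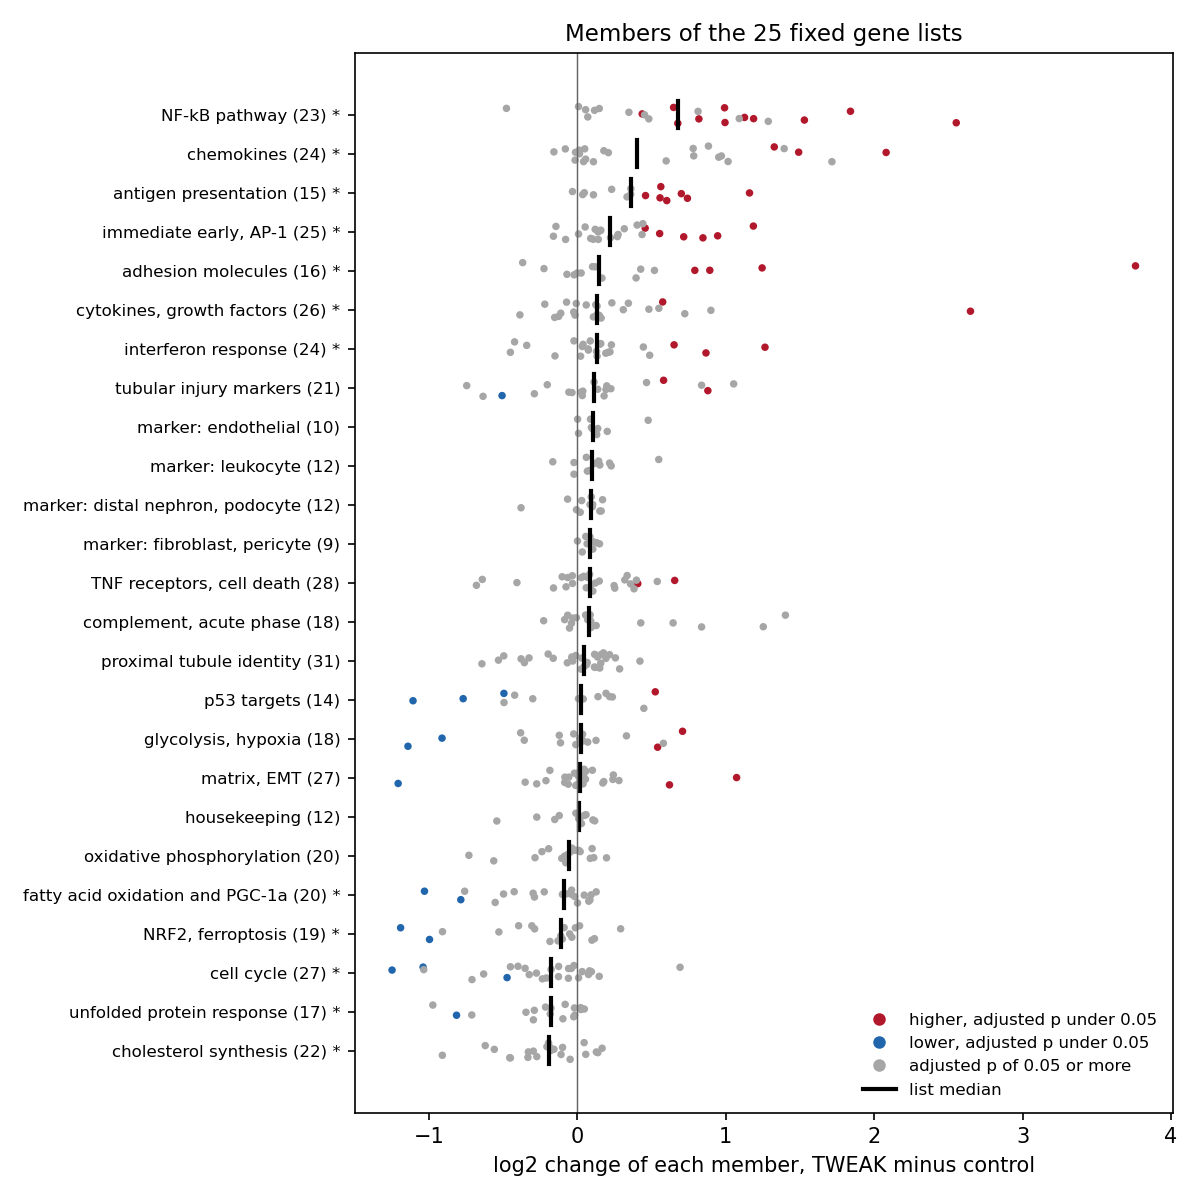
Each point is the log2 change (TWEAK minus control) of a member of 1 of the 25 gene lists, red or blue where it was higher or lower at adjusted p under 0.05 over all genes and grey otherwise; black bars are list medians, numbers in brackets the members measured, and a star marks the 12 lists called by camera with the preset correlation. Medians run from -0.19 for cholesterol synthesis to 0.68 for the NF-kB pathway.

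Among the 10 largest falls, Cul4b fell by 1.61 (SE 0.21) and Lpp by 1.44 (SE 0.27), with limma's Benjamini-Hochberg adjusted p at 0.0209 and 0.0391. The kinetochore protein Spc25 fell by 1.40 (SE 0.26), the spindle kinesin Kif11 by 1.35 (SE 0.28), the exonuclease Eri2 by 1.31 (SE 0.25), the lysosomal membrane protein Ostm1 by 1.30 (SE 0.23), the kinase Map4k3 by 1.30 (SE 0.23), the mitochondrial RNA enzyme Pnpt1 by 1.28 (SE 0.23), the pseudogene Smarca5-ps, which the deposited file names Vmn2r-ps14, by 1.26 (SE 0.25) and the imprinted gene Peg3 by 1.26 (SE 0.25). With the main axis of variation among arrays removed, all but Cul4b shrank by over 1.5 times, Lpp and Spc25 to -0.81, Map4k3 to -0.73, Ostm1 to -0.71, Eri2 to -0.70, Pnpt1 to -0.66, Smarca5-ps and Peg3 to -0.62 and Kif11 to -0.60. For Lpp only the brightest of 3 probe sets showed this size, the others differing by 0.01 and -0.23. Every one of these 10 lost its call without TWEAK 1, and without control 2 limma called 0 genes lower, with 3502 at an unadjusted p under 0.05 in either direction.

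Cell cycle genes were called lower as a list, with 3 of 27 members lower over all genes and 10 lower and 1 higher adjusted over the list alone (median -0.18, camera adjusted p = 7.08e-04). The call had adjusted p = 0.333 with an estimated correlation. The 3 became 6 without control 1, 1 without TWEAK 2 and 0 without any 1 of the other arrays, with 9 to 11 lower at an unadjusted p under 0.05 in limma. The spindle checkpoint kinase Bub1 fell by 1.25 (SE 0.26), the mitotic kinesin Cenpe by 1.04 (SE 0.21) and cyclin Ccnb2 by 0.47 (SE 0.09), while Top2a differed by -1.03 (SE 0.25). For Top2a this is the brightest probe set, and the dimmer ones differed by -0.26 and 0.34. Fatty acid oxidation had 2 of 20 members lower, 5 adjusted over the list alone (median -0.09, camera adjusted p = 0.00208, and adjusted p = 0.274 with an estimated correlation). Its falling members were Cpt1a and the medium-chain dehydrogenase Acadm, by 0.79 (SE 0.14), and Hadhb differed by -0.50 (SE 0.11). The fatty acid oxidation median was -0.13 without control 2, -0.15 without TWEAK 3 and -0.05 with array weights. Camera called the list in each.

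Cholesterol synthesis was called lower (median -0.19, camera adjusted p = 0.00395, and adjusted p = 0.583 with an estimated correlation) although limma called 0 of its 22 members, and 0 adjusted over the list alone, with 5 lower at an unadjusted p under 0.05. The call was lost without control 2 (adjusted p = 0.0576), without TWEAK 3 (0.0641, median -0.06) and with the main axis removed (0.267). The axis removal moved the median to -0.11 (quartiles from -0.33 and -0.06 to -0.16 and -0.01). The smallest p in the cholesterol list belonged to Insig1, at -0.45 (SE 0.13), and Idi1, at -0.91 (SE 0.27). The unfolded protein response had 1 of 17 members lower, the endoplasmic reticulum chaperone Dnajb9, which fell by 0.81 (SE 0.14), and 4 lower adjusted over the list alone (median -0.18, camera adjusted p = 0.00187, and adjusted p = 0.454 with an estimated correlation). Antioxidant and ferroptosis genes had 2 of 19 members lower, 6 adjusted over the list alone (median -0.11, camera adjusted p = 0.00251, and adjusted p = 0.274 with an estimated correlation). These were the iron exporter Slc40a1, which fell by 1.19 (SE 0.19), and the lipid enzyme Acsl4, which fell by 1.00 (SE 0.21). With the main axis removed the call of the antioxidant and ferroptosis list was lost at adjusted p = 0.101, with the median still at -0.11 (quartiles from -0.35 and -0.03 to -0.27 and 0.01). Limma's fry, which asks whether a list moves on balance to either side without comparing it with other genes, called 4 of the 25 lists: NF-kB, antigen presentation and fatty acid oxidation (adjusted p = 0.0177 each) and the antioxidant and ferroptosis list (0.0241). With only genes brighter than the median gene tested, camera called none of the 5 lower lists and not the interferon list, at adjusted p of 0.0565 to 0.0925. Among these brighter genes the median was 0.99 for 12 chemokines, 0.52 for 9 adhesion molecules and 0.34 for 9 cytokines and growth factors, against 0.40, 0.14 and 0.13 in the full lists.

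Camera did not call the other 13 lists. Proximal tubule identity had 0 of 31 members past limma's test, and 0 adjusted over the list alone, with 3 higher and 5 lower at an unadjusted p under 0.05 (median 0.04, mean -0.02). The median was 0.10 without control 1, -0.07 for the 13 members brighter than the median gene and -0.03 with the main axis removed. The smallest p in this list belonged to the endocytic receptors Cubn, at -0.33 (SE 0.08), and Lrp2, at -0.64 (SE 0.18). Tubular injury markers had 2 of 21 higher, among them Clu (0.58, SE 0.11), and 1 lower, the matrix protein Spp1, which fell by 0.51 (SE 0.08), with 3 higher and 1 lower adjusted over the list alone. Matrix and mesenchymal genes had Tgfb1 (0.62, SE 0.09) and the gelatinase Mmp9 (1.07, SE 0.22) higher and Thbs1 lower, by -1.21 (SE 0.23), of 27 measured, and the same numbers adjusted over the list alone. Of 28 TNF receptor and cell death genes 2 rose, the death domain adaptor Fadd (0.41, SE 0.08) and the death receptor Tnfrsf10b (0.66, SE 0.14), and 3 were higher and 1 lower adjusted over the list alone. Camera gave these lists adjusted p of 0.806 for tubule identity, 0.485 for injury, 0.722 for matrix and 0.118 for cell death, which cyclic loess brought to 0.0409.

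Targets of p53 moved both ways: the cyclin Ccng1 fell by 1.11 (SE 0.19), the stress-induced factor Gdf15 by 0.49 (SE 0.09) and Sesn1 by 0.77 (SE 0.14), whereas the nuclease Aen rose by 0.53 (SE 0.10), and adjusted over the list alone 2 of 14 were higher and 5 lower. Among 18 glycolysis and hypoxia genes the prolyl hydroxylase Egln3 rose by 0.71 (SE 0.08) and the glycolytic regulator Pfkfb3 by 0.54 (SE 0.10), while Hif1a fell by 1.14 (SE 0.24) and Bnip3 by 0.91 (SE 0.16), and 3 were higher and 4 lower adjusted over the list alone. The p53 and glycolysis lists had a median of 0.02 each but means of -0.13 and -0.03 and a downward camera direction, and fry gave the glycolysis list an upward direction. With the main axis removed these medians were -0.21 and -0.09. The p53 median was -0.07 without control 2 and 0.15 without TWEAK 2. Complement and acute phase genes had 0 of 18 past limma's test, with 2 higher and 1 lower at an unadjusted p under 0.05, and 2 higher adjusted over the list alone, Il1rn (0.65, SE 0.15) and Cfb (0.43, SE 0.11). With the replicate block 5 were higher and 1 lower at an unadjusted p under 0.05 in limma. The median was 0.08 in the full complement list. When only genes brighter than the median gene were tested, its 5 brighter members had a median of 0.84, with 1 called higher and a camera adjusted p of 0.0565. Oxidative phosphorylation had 0 of 20 members past limma's test, with 4 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone, its smallest p being that of Ndufs1 at -0.73 (SE 0.18). Camera gave an adjusted p of 0.405 for the p53, 0.870 for the glycolysis, 0.368 for the complement and 0.118 for the oxidative phosphorylation list. The last was called lower after cyclic loess (0.0479) and without TWEAK 3 (0.00953, median -0.10 instead of -0.05). Without TWEAK 1 the oxidative phosphorylation median was -0.01, at a camera adjusted p of 0.615.

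Of 12 housekeeping genes limma called 0, with 2 lower at an unadjusted p under 0.05 and 1 adjusted over the list alone, Hprt, at -0.54 (SE 0.12); the list had a median of 0.01, a mean of -0.06 and a camera adjusted p of 0.502. Markers of leukocytes, endothelium, fibroblasts with pericytes, and distal nephron with podocytes had 0 members past limma's test, of 12, 10, 9 and 12 measured. At an unadjusted p under 0.05, 1 leukocyte marker and 2 endothelial markers were higher and 1 distal nephron or podocyte marker was lower, and adjusted over the list alone only the leukocyte marker Cd14 passed, at 0.55 (SE 0.14). Medians of these marker lists were 0.10, 0.10, 0.09 and 0.09, and camera gave adjusted p of 0.118, 0.0637, 0.266 and 0.561. With the main axis removed the medians were -0.04, 0.02, -0.01 and -0.06. Without TWEAK 3 the endothelial list was called higher at 0.0320.

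The authors' deposited table listed 107 probe sets at a false discovery rate under 0.05, 78 higher and 29 lower under TWEAK, which belong to 104 named genes. All 104 of these genes were called in the test by gene. In the authors' deposited table Vcam1 had a ratio of 14.1, and the ratio is of means of unlogged values, so that its direction differs from that of the log2 means at 276 probe sets.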

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

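Among probe sets that carry no single gene symbol and so lie outside the comparison by gene, 3 were higher under TWEAK than in the control arrays when all probe sets were tested together, a signal in data not otherwise reported. Their log2 differences were 1.25 for 1 and 1.14 for the others, with limma's Benjamini-Hochberg adjusted p at 0.0387 for each, and the TWEAK value was above every control value on all arrays. Those at 1.14 hold identical values on all 6 arrays, so they are a single signal. What these probe sets measure is not known from the files, and no explanation was tested. Groups of 3 arrays are too small for single arrays to be tested as outliers.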

How the results depend on the processing

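Removal of the array axis, array weights and counting identical genes once were chosen after seeing the data, as was the correlation over variable genes. No list that was called changed direction, and 660 of the 661 changed genes kept their sign in every setting run by gene, the exception being 1 gene with the mean of all probe sets. Most of this was fixed beforehand. All 283 higher and 378 lower genes had groups of arrays that did not overlap, so neither leaving out an array nor array weights could turn a sign. The block, the trend and robust fit and testing fewer genes leave each difference as it was. Only the probe set mean, median centring, cyclic loess and axis removal could turn a sign. The balance of the calls did turn. More were lower in the comparison as reported, and more were higher with median centring (308 higher, 269 lower), after cyclic loess, with the replicate block and without control 2, control 3 or any 1 of the TWEAK arrays. The trend and robust, probe set mean, median centring and identical gene settings kept the count within 1.5 times of 661 (577 to 881), and 344 further genes had an adjusted p between 0.05 and 0.06. With only genes brighter than the median gene, 1020 changed (643 lower) and 6 lists were called; fewer genes were then tested. Cyclic loess gave 252 (183 higher, 69 lower, 56 by 2-fold); the cause was not tested. Axis removal gave 1864 (721 higher, 1143 lower, 41 by 2-fold); it lowers the spread within groups by its own construction, so its higher count is no evidence. Array weights gave 3223 (1114 higher, 2109 lower, 162 by 2-fold), with control 2 weighted at 5.60 and the other arrays at 0.530 to 0.945; the cause was not tested. All probe sets tested 1 by 1 gave 107 (78 higher, 29 lower, 41 by 2-fold), and the authors' deposited table gave 107 (78 higher, 29 lower, 40 by 2-fold); more features were tested, among them 2894 with no symbol. Leaving out each array in turn gave 1 to 1876 changed genes, 1 to 464 higher, 0 to 1412 lower and 1 to 350 by 2-fold, with 3391 to 5313 genes at an unadjusted p under 0.05 in limma, and 10 to 13 lists. The 12 list calls became 0 with an estimated correlation and 4 with fry. Of 65 genes past the threshold that the naming rule took, all kept their sign in every alternative and 1, Spib, was called in every one. Their signs, too, could not turn with an array left out or where a setting leaves the difference as it was. The deposited series values equalled the workbook's, so a second run on them was not made. No signal over background was used, so the detection of dim genes was not judged.

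With the replicate number as a block, 207 genes changed (122 higher, 85 lower), 167 of them among the 661, and the same number of lists, 12, was called. With the block 7 chemokines, 3 antigen presentation genes, 2 immediate early genes and 1 cell cycle gene were higher, and limma called 0 cell cycle genes lower, with 10 at an unadjusted p under 0.05. The same-numbered control and TWEAK arrays had residual correlations across all genes of 0.20, 0.36 and -0.07. Of the 6 arrays, 3 correlated best with their own number, so the numbers were not taken as pairs. The value for number 3 cannot reject pairing, however. Control 3 and TWEAK 3 lay at opposite ends of the main axis of variation among arrays (scores of -32.3 and 26.2), which held 43.4% of the variance within groups. Over 475 genes of large within-group spread the correlations were 0.30, 0.60 and 0.26, and the highest of differently numbered arrays was 0.15. The lowest, 0.263, missed the bound of 0.3 set for a shared experiment. With the array axis removed the correlations were 0.41, 0.70 and 0.73 over these genes (differently numbered up to 0.52) and 0.16, 0.41 and 0.63 over all genes (up to 0.62), and of the 6 ways to pair the arrays the numbered one had the highest mean in both. These values point towards a shared experiment, but taking out an axis of so few arrays itself alters their correlations, so whether the numbers pair the arrays stays open.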

Other observations

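All tests in this part, the other splits of the arrays included, were chosen only after the results had been seen, and so were the genes and groups named here that the text has not yet named. Small nucleolar RNAs, which guide the modification of ribosomal RNA, were mostly higher under TWEAK: 68 of 70 had a positive log2 change, 8 passed limma's test over all genes, and the median was 0.51. Snora41 rose by 1.09 (SE 0.15), Snord73a by 0.78 (SE 0.10) and Snord68 by 0.78 (SE 0.16). Ribosome biogenesis genes, a list put together after seeing which genes changed, had 9 of 49 higher and a median of 0.24, with the RNA polymerase I subunit Polr1b at 0.79 (SE 0.11) and the processing factors Nle1 at 0.90 (SE 0.13) and Ppan at 0.86 (SE 0.11). Kinetochore and mitotic motor genes, put together in the same way, had 8 of 39 lower and a median of -0.60, where lists matched on the within-group differences and level, described below, had -0.46 (95% of draws from -0.55 to -0.34). With an estimated correlation camera gave each of these groups an adjusted p of 0.146.

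Some inflammatory genes differed more between arrays of the same group than between the groups. The neutrophil protein Lcn2 was at 11.58, 11.41 and 5.66 in control 1, 2 and 3 and at 12.07, 12.04 and 7.04 in TWEAK 1, 2 and 3 (log2). The complement gene C3 was at 9.98, 10.55 and 6.60 against 10.86, 11.42 and 8.61, and the chemokine Ccl2 at 10.70, 10.89 and 8.41 against 11.89, 11.90 and 11.36. Ms4a4d was at 9.48 in control 2 and 8.97 in TWEAK 2 and between 3.84 and 4.28 on the other arrays. Within each group Lcn2, C3 and Ccl2 were lowest in number 3, and at every number these genes were higher under TWEAK. Ms4a4d was high in number 2 of both groups. Such patterns by number also point towards a shared experiment of same-numbered arrays, but these genes were picked after their values were seen. None of Lcn2, C3, Ccl2 and Ms4a4d passed limma's test between the groups without a replicate block, which ignores this pattern by number.

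The leukocyte-linked genes Spib, Cd74 and Irf5 rose by 1.71 (SE 0.11), 1.44 (SE 0.22) and 1.49 (SE 0.13). Of the 12 leukocyte markers fixed beforehand the median log2 change was 0.10 and the highest 0.55, that of Cd14, which was over the bound of 0.5 set for excluding leukocytes in the TWEAK cultures, while Ptprc changed by 0.07 and Lyz2 by 0.23 at low values. The markers did not rise together, and the cultures were of a tubular epithelial line, to which the design adds no leukocytes. Cd14 was already at 7.92 in the control cells. Ptprc, at 4.41 in control and 4.48 in TWEAK cells, lay below the lower quartiles of the arrays (4.65 to 4.73). Dim markers cannot decide alone, so by these values the source of the 3 transcripts stays open.

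The genes that fell followed a gradient that also ran within the control arrays. Of them, 95.5% were higher in control 3 than in control 1, against 37.9% of all genes, and the change under TWEAK correlated with control 3 minus control 1 across all genes at r = -0.64, where independent errors of equal size would give no correlation. Removing the first axis of within-group variation moved the median of the fallers from -0.71 to -0.49 and that of the risers from 0.65 to 0.52. Scores on that axis were 6.69, -15.6 and -32.3 for control 1, 2 and 3 and 16.6, -1.56 and 26.2 for TWEAK 1, 2 and 3. The removal also took out this difference between the groups, so a TWEAK effect along the axis would shrink as well. These smaller sizes do not tell the gradient from the treatment. Of genes named above that had passed the threshold, the removal moved Cx3cl1 to 0.76, Mmp9 to 0.62, Myc to 0.53, Madcam1 to 0.49, Junb to 0.44 and Aen to 0.35. It moved Ccng1 to -0.73, Bub1 to -0.64, Cenpe to -0.57, Hif1a to -0.52, Acsl4 to -0.48 and Acadm to -0.46. All of these moved by over 1.5 times. Some named genes not past the threshold shrank further in an alternative setting. Idi1 went from -0.91 to -0.23, Lrp2 from -0.64 to -0.20, Insig1 from -0.45 to -0.21 and Ndufs1 from -0.73 to -0.31. For the fatty acid oxidation list, at a median of -0.09, the part of the gradient stays open: 25.8% of lists matched on within-group differences and level were as low (10.5% without matching on level). With the axis removed the median was -0.13 and camera still called the list, at an adjusted p of 0.00865. That call cannot decide, because the removal lowers the spread within groups by its own construction. For the antioxidant and ferroptosis list, at -0.11, 15.5% of matched lists were as low (12.8% without level), so the part of the gradient stays open as well. With the axis removed the call was lost at 0.101 while the median stayed at -0.11, which cannot decide either. The cell cycle list, at -0.18, was lower than all but 1.08% of matched lists, whose median was -0.05. The draws took each gene on its own, without the correlation among cell cycle genes, so their medians can spread too little. Camera with an estimated correlation (adjusted p = 0.333) and fry (0.0564) did not call the list, so the part of the gradient stays open here too. Whether the gradient is RNA quality, labelling or the state of the cells was not tested.

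The same gradient is a candidate explanation for the lists that rose, since 85.9% of the genes that rose were lower in control 3 than in control 1. The NF-kB list had a median of 0.68 against 0.11 for matched lists (95% of draws from 0.03 to 0.19), the antigen presentation list 0.36 against 0.07 (-0.02 to 0.15) and the small nucleolar RNAs 0.51 against 0.06 (0.01 to 0.12). For each of these, 0.01% of the matched lists were as high, the smallest share that 10000 draws can give, with or without matching on level, which was added after the first draws were seen. For the NF-kB and antigen presentation lists this argues against the gradient as their whole cause. Matching on single-array differences is incomplete, however, and the draws took each gene on its own, without the correlation within a list. The small nucleolar RNAs were picked after many groups of gene names had been looked through, so their share draws no conclusion. For the ribosome biogenesis genes the share was also 0.01%, but it decides nothing, since they were chosen for the pattern; a difference in the labelling of short RNAs was not tested.

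Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. As many genes as in the real split, 661, came from 1 split, the real one, and the highest count among the others was 0 (with up to 3269 genes at an unadjusted p under 0.05 in limma); for changes of at least 2-fold the real count was 104 and the highest other 0, from 1 split as well. For gene lists 1 split gave as many as 12, and the highest other split, control 1, control 3 and TWEAK 3 against the rest, gave 10.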
